A study of Mus musculus with 4 samples.

How the data were processed

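The 4 matrices of the series were used as deposited. They hold UMI counts per gene symbol and cell barcode. Per the submitters' processing notes, reads were aligned to the mouse genome mm10 and Seurat was used, with no version given. The counts were made by the authors before deposit, and alignment and counting were not repeated here. Per the labels' protocols, islets of several mice were pooled for each sample, cells were encapsulated by an inDrops method and sequenced on an Illumina NovaSeq instrument, about 3500 cells were aimed at per fraction, and 10% human K562 cells were added. Cells with and without the tdT reporter were sequenced together. The K562 cells could not be called, since the matrices name mouse genes only, and the reporter has no gene name in them. Samples were read as 2 mutants and 2 controls from their titles, and every fit compared sums of cells per sample, so p-values measure the spread between 2 pools per group and not between mice. Groups, comparisons, gene lists, marker genes and the rule for naming genes were fixed before the data were examined.

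The values were found to be whole-number counts, with highest values of 4089, 4093, 4078 and 4079, near the 4096 sequences of a 6-base UMI. In all 11114 barcodes and 21594 gene symbols were read. Cells with at least 500 genes and under 20% mitochondrial counts were kept (6995). Scrublet, run per sample at an expected doublet rate of 6%, marked 28 barcodes, which were removed. That is 0.400% of the cells, so the caller cannot be taken to have worked, and doublets probably remain. The 6967 cells left were scaled to 10000 counts, logged, reduced with 1996 variable genes to 30 principal components and clustered by the Leiden method at resolution 1 on 15 neighbours, with no integration across samples (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9). A cluster took the class with most markers among its 10 leading genes, or else the class with the highest mean marker level. It stayed unnamed where markers of another class led, where fewer than 3 markers were detected or where its own markers made up under 0.5% of its counts. That limit of 0.5% and the final form of the naming rule were set after the clusters had been seen. It left 54, 94, 216 and 346 cells of mutant 1, mutant 2, control 1 and control 2 without a class. The classes are rebuilt names, and a difference from the authors' own cell types may come from that.

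Counts were summed per sample and class and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by quasi-likelihood F tests after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Levels are TMM-scaled counts in CPM, that is per 1e6 counts of the sum. DESeq2 1.42.0 and limma-voom were the other tools. Leaving out 1 sample left 1 residual degree of freedom, and the prior degrees of freedom, 7.34 for beta-like cells with all samples, became infinite in most of those fits, where every gene has the common spread. For beta-like against alpha-like cells the difference of the mutant effects was tested, with the sample as a block. The named genes were the 12 with the largest rise and the 12 with the largest fall in beta-like cells among those that passed with an average log2 CPM of at least 5 and both mutants on the same side of both controls, and 6 each way in alpha-like cells and in the difference. From each list up to 4 members with the lowest p were named if they passed over all genes or over the list alone. Other genes are named as chosen after their values were seen.

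The 28 lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. They were Atf4 targets, tRNA synthetases, ribosomal proteins, translation factors, endoplasmic reticulum chaperones, beta cell identity, granules and exocytosis, genes low in mature beta cells, other islet hormones, fatty acid synthesis, fatty acid oxidation and cholesterol synthesis. The others were nuclear respiratory chain, mitochondrially encoded genes, antioxidants, immediate early genes, cell cycle, p53 and apoptosis, autophagy and lysosome, interferon and antigen presentation, sex-linked genes, and markers of acinar, endothelial, mesenchymal, immune, duct, erythroid and alpha cells. The pattern for mitochondrially encoded genes had a typing error and was corrected to its written definition after the data were seen. Shares of cells were compared by exact permutation of the 4 samples, with Clopper-Pearson intervals per sample. Gene positions are from GENCODE vM21 on GRCm38, which placed 97.2% of the genes tested in beta-like cells. The fits were tested on simulated data, drawn from negative binomial distributions with the library sizes and dispersions of the real sums. Each gene had a single mean over all sums, shared by beta-like and alpha-like sums in the test of the difference. Weaker genes are not covered, since only genes above a minimum mean level were changed, 200 in all, by 2-fold or 4-fold. Of these, 92% and 100% were found in beta-like cells with 20 false calls, 55% and 88% with 8 in alpha-like cells, and 44% and 87% with 6 in the difference. A change of 2-fold in alpha-like cells would therefore often be missed. The simulated pools of a group did not differ as mutants 1 and 2 did. The shares found in beta-like cells thus do not cover genes whose levels differed between the mutants. In the real beta-like sums Atf4, with a log2 change of −2.65, did not pass. Asns, Slc7a5, Psph and Eif4ebp1, which fell by more than 2-fold, did not pass over all genes either.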

Results

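Single-cell RNA was counted in dissociated pancreatic islets of 2-month-old mice. The 4 samples formed 2 groups of 2. The Atf4 mutants carried both floxed Atf4 alleles together with the Cre recombinase driver Ins1Cre, and the controls carried the floxed alleles and no Cre. Atf4 is a transcription factor of the integrated stress response, and Ins1Cre directs recombination to insulin-producing beta cells. The series asks what Atf4 contributes to the identity and function of beta cells. Each sample was a pool of islets, given as 2 males and 2 females in the series' design text and as 3 to 4 mice in the extraction protocol. The edgeR tests of all 4 samples therefore rest on the spread between pools, 2 per group, and not between mice. The deposited matrices held 2352 and 2597 barcodes for mutants 1 and 2 and 3272 and 2893 for controls 1 and 2. Their counts of unique molecular identifiers (UMIs) came to 13706563 and 15453658 for the mutants and to 16729747 and 17655893 for the controls. After filtering, 1394, 1711, 1994 and 1868 cells remained, with median UMI counts of 5786.5, 5757, 5189.5 and 5558 per cell. The replicates of each group differed by more than counting noise (chi-square per degree of freedom 9.56 for the mutants and 11.6 for the controls), so none was a second copy of another.

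Clustering gave 13 clusters. Marker genes fixed before the data were examined named 3932 cells beta-like, with 802, 885, 1242 and 1003 cells in mutant 1, mutant 2, control 1 and control 2. They named 563 cells alpha-like, 659 delta-like, 550 PP-like, 324 endothelial-like, 207 macrophage-like and 22 stellate-like. The beta-like clusters separated the groups. Clusters 0 and 4 held 84.9% and 71.8% of the beta-like cells of mutants 1 and 2, against 2.01% and 5.78% in controls 1 and 2. Clusters 1 and 8 held 4.24% and 8.70% in the mutants and 64.8% and 63.2% in the controls. Cluster 3, with the fewest genes per cell of the beta-like clusters, held the rest. Beta-like counts summed per sample came to 9192048 and 9563010 UMIs for mutants 1 and 2 and to 11581622 and 11547786 UMIs for controls 1 and 2.

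The targeted gene separated the groups, and the mutants from each other. Atf4 (chromosome 15, 80255184 to 80257541, plus strand, GRCm38, the assembly also named mm10) stood at 1.83 CPM in the beta-like cells of mutant 1 and at 117 CPM in those of mutant 2, against 362 CPM in control 1 and 379 CPM in control 2 (18, 1117, 3901 and 4356 UMIs). The log2 change was −2.65 ± 1.03 (SE, n = 2 per group), which did not pass the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.277). With 1 sample left out, its group holds 1 sample and the spread comes from the other group alone, so such fits give size and direction and do not offset that result. The log2 change was −1.67 (edgeR adjusted p = 0.00111) without mutant 1, −7.68 (1.26e-07) without mutant 2, −2.68 (1.75e-45) without control 1 and −2.61 (2.95e-40) without control 2. Without either control, edgeR gave every gene the common spread in place of its own, so the last 2 p-values leave out the gap between the mutants. Ins1 (chromosome 19, 52264297 to 52265476, plus strand), the insulin gene at whose locus the driver was named, had 93674 and 124482 CPM in mutants 1 and 2 and 151932 and 140853 CPM in controls 1 and 2. Its log2 change of −0.42 ± 0.119 (SE, n = 2 per group) had an edgeR adjusted p of 0.151. With the same limits it was 0.162 without mutant 1, 0.000958 without mutant 2, 0.00907 without control 1 and 1.33e-08 without control 2. Ins2 (chromosome 7, 142678656 to 142743381, minus strand) stood at 189845, 214456, 230927 and 201137 CPM (log2 change −0.10, SE 0.0888, edgeR adjusted p = 0.669). The sign of this difference turned with library totals as the only scaling (0.01) and without control 1 (0.00386). The highest single value per library, 4078 to 4093, lay close to the 4096 different UMIs that 6 bases allow, so the insulin genes were counted near saturation in the deepest cells.

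Per-cell counts showed how mutant 2 differed. Among beta-like cells with more than 8000 UMIs, a limit chosen after the data were seen, 97.3% of 400 cells of mutant 1 had no Atf4 count (95% Clopper-Pearson interval 95.1 to 98.6%). The share was 51.0% of 457 cells in mutant 2 (46.3 to 55.7%), 2.44% of 532 cells in control 1 (1.31 to 4.14%) and 2.72% of 515 cells in control 2 (1.49 to 4.52%). At least 3 Atf4 counts were found in 0, 134, 418 and 414 of these cells. Clusters 1 and 8, where most beta-like cells of the controls lay, held 77 beta-like cells of mutant 2, fewer than those 134. Some of the 134 therefore lay in clusters 0, 3 or 4, so the clusters need not follow the Atf4 counts alone. Clustering used no integration, and a difference between libraries could enter it as well. Among the deep cells of mutant 2 whose sex could be told, 58.8% of those with no Atf4 count had Xist and no Y-linked count, against 1.74% of those with at least 3 (Fisher's exact test on both sides, p = 6.16e-27). In beta-like cells with Xist and no Y-linked count, Atf4 stood at 0.678, 9.90, 349 and 454 CPM in mutant 1, mutant 2, control 1 and control 2, a log2 change of −6.41 ± 0.454 (SE, n = 2 per group, edgeR adjusted p = 2.65e-05). In cells with Y-linked counts and no Xist it stood at 2.96, 188, 388 and 355 CPM (−1.94 ± 0.951, edgeR adjusted p = 0.607). The insulin counts followed the Atf4 counts within mutant 2: Ins1 made up 25.2% of insulin counts, corrected for UMI collisions, in cells with no Atf4 count and 35.0% in cells with at least 3, next to 24.6% in all deep cells of mutant 1 and 34.6% and 35.3% in those of controls 1 and 2. The cells compared within mutant 2 differed in depth, with median UMI counts of 15159 and 18129.5.

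**Figure D1:**
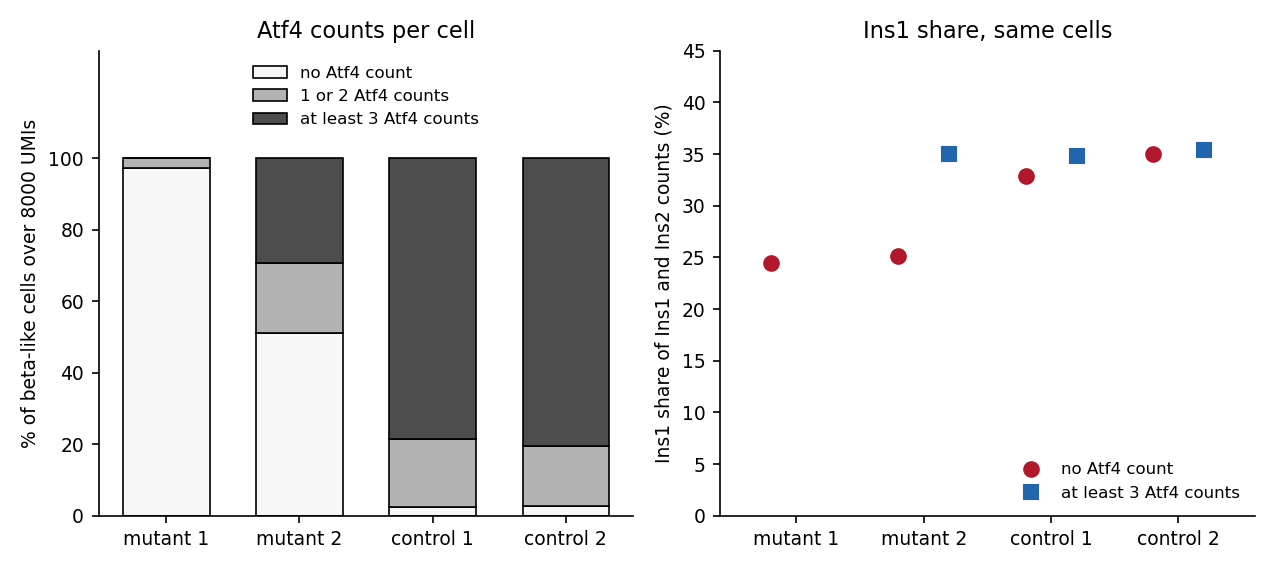
Left, the percentage of beta-like cells with more than 8000 UMIs that had 0, 1 to 2 or at least 3 Atf4 counts, per sample; right, the percentage of insulin counts that were Ins1 in cells with no Atf4 count and with at least 3, per sample. Mutant 2 held both kinds of cell (51.0% with no Atf4 count, 29.3% with at least 3), and its 2 kinds of cell had Ins1 shares of 25.2% and 35.0%.

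In beta-like cells the cyclin-dependent kinase inhibitor Cdkn1a (p21) rose from 21.4 ± 6.65 CPM in controls to 390.3 ± 133 CPM in mutants (mean ± SD, n = 2 per group), a log2 change of 4.19. Cyclin G1, Ccng1, rose from 51.3 ± 1.66 to 277 ± 85.5 CPM. Cacna1i, a T-type calcium channel subunit whose gene starts 29.7 kb downstream of Atf4 on the same strand, rose from 1.39 ± 0.127 to 71.5 ± 26.0 CPM. Neuronatin, Nnat, fell from 146 ± 7.60 to 28.7 ± 5.95 CPM, and neuropeptide Y, Npy, fell from 76.8 ± 20.8 to 13.5 ± 7.91 CPM. Of 13443 genes tested, 78 rose and 36 fell with the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), and 1964 had an unadjusted p under 0.05. With library totals as the only scaling, which moved the median of all genes by 0.11, 184 rose and 42 fell. Ins1Cre was present in the mutants alone, so the driver allele and the loss of Atf4 changed together.

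Of the genes named by the fixed rule that rose, Cdkn1a (chromosome 17, 29090976 to 29100727) had a log2 change of 4.19 ± 0.281 SE (edgeR adjusted p = 0.000240) and Ccng1 (chromosome 11, 40748552 to 40755311) of 2.43 ± 0.201 (0.00100). Others were Zmat3, an RNA-binding zinc finger protein (1.47 ± 0.141, 88.6 against 32.0 CPM, edgeR adjusted p = 0.00253), Trp53inp1 (1.14 ± 0.191, 87.7 against 39.8 CPM, adjusted p = 0.0307) and Rps27l (1.18 ± 0.214, 127 against 56.1 CPM, adjusted p = 0.0421). Cacna1i (chromosome 15, 80287238 to 80398279) had a log2 change of 5.67 ± 0.314 (edgeR adjusted p = 9.33e-05). The opioid precursor Pdyn (1.78 ± 0.263, 189 ± 17.2 against 55.1 ± 25.9 CPM, edgeR adjusted p = 0.0213) rose with it. So did the cyclic nucleotide phosphodiesterase Pde10a (1.74 ± 0.150, 222 ± 31.4 against 66.6 ± 7.61 CPM, edgeR adjusted p = 0.00112) and the exocyst subunit Exoc4 (1.19 ± 0.128, 301 against 132 CPM, adjusted p = 0.00446). Gc, the vitamin D binding protein, rose by 1.67 ± 0.175 (57.0 ± 12.1 against 17.9 ± 2.43 CPM, edgeR adjusted p = 0.00394). The long noncoding RNAs A330008L17Rik (2.75 ± 0.184, 89.0 ± 12.1 against 13.2 ± 3.34 CPM, edgeR adjusted p = 0.000240) and Gm6999 (1.24 ± 0.189, adjusted p = 0.0228) completed the set.

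Among the named genes that fell, Npy had a log2 change of −2.51 ± 0.329 (SE, n = 2 per group, edgeR adjusted p = 0.0124), Nnat of −2.35 ± 0.159 (0.000240), the retinol carrier Rbp4 of −1.37 ± 0.219 (0.0266), and the secreted glutathione peroxidase Gpx3 of −1.06 ± 0.133 (0.0107). Rbp4 was among the leading genes of the delta-like cluster, and Gpx3 among those of the PP-like and alpha-like clusters. Before TMM scaling Rbp4 had 23.9 to 82.2 CPM in beta-like sums and 1405 to 2163 CPM in delta-like sums. RNA of other islet cells in beta-like barcodes was therefore not told apart from a change in beta cells for these genes. Pancreatic polypeptide, Ppy, fell from 559.5 to 240.0 CPM (−1.22 ± 0.188, edgeR adjusted p = 0.0230) and peptide YY, Pyy, from 623 to 301 CPM (−1.05 ± 0.136, adjusted p = 0.0122). These 2 changed in settings that treated doublets otherwise, which also redrew the clusters and classes. Ppy was 0.01 with called doublets kept and 0.12 with the highest doublet scores removed, where Pyy was 0.28. With called doublets kept, PP-like cells went from 120, 170, 157 and 103 in mutant 1, mutant 2, control 1 and control 2 to 51, 66, 126 and 73. With the highest scores removed no PP-like class formed, so doublets and class borders were not told apart. Th, which makes the catecholamine precursor L-DOPA, fell by 0.89 on the log2 scale and Aars, the alanyl-tRNA synthetase, by 1.07 (47.7 ± 14.5 against 99.9 ± 4.47 CPM). The immediate early or feedback genes Socs3, Junb and Ier2 fell by 1.37, 0.92 and 0.87, and the predicted gene Gm17660 by 1.47 (edgeR adjusted p between 0.0232 and 0.0367 for these 6 genes).

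**Figure D2:**
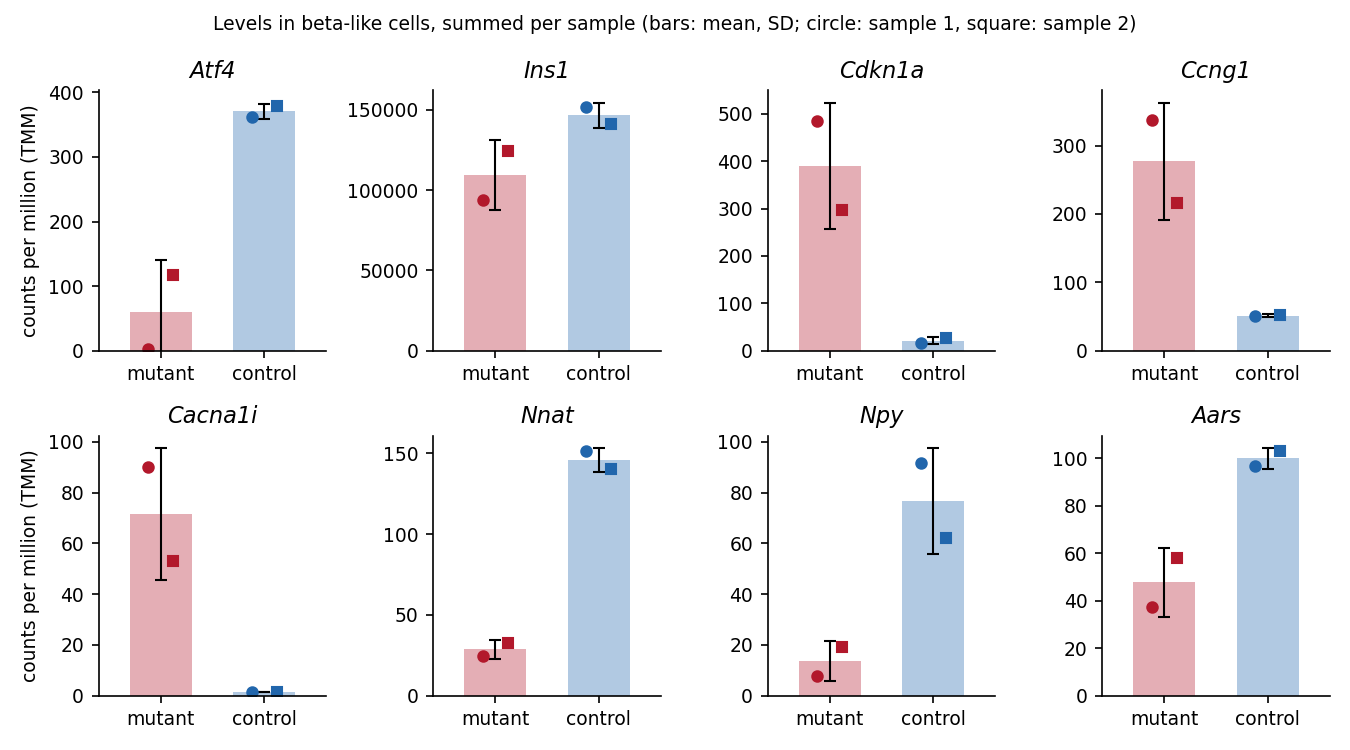
Levels of 8 genes in beta-like cells in CPM on linear axes, with bars for the mean of each group, points for the 2 samples and error bars for 1 SD, ending at 0 where they would go below it. Cdkn1a, Ccng1 and Cacna1i were higher in both mutants than in both controls and Nnat, Npy and Aars lower, while Atf4 in mutant 2 (117 CPM) stood between mutant 1 (1.83 CPM) and the controls.

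The size of the set changed whichever sample was left out. The 114 genes became 78 without mutant 1, 296 without mutant 2, 503 without control 1 and 493 without control 2. Of the 114, 55, 101, 114 and 114 were kept. Without either control edgeR used the common spread for every gene, so the counts of 503 and 493 do not measure stability. Without mutant 1, the calls of Gm6999, Rps27l, Aars, Junb, Th and Ier2 among the 24 genes ended (edgeR adjusted p 0.0543 to 0.0739), as did those of Rpl3, Ppargc1a, Mt2, Mt1 and Bax among the list members below (0.0696 to 0.142). Of the 24 genes, 5 kept their call in every other setting that used all 4 samples, and 9 in every one but cells with Y-linked counts and no Xist. In those cells 6 of the 24 kept their call and 18 lost it, with no change of sign. Atf4 stood there at 188 CPM in mutant 2 against 2.96 CPM in mutant 1, so the mutants were unlike in the targeted gene. Whether this ended the calls was not tested. All 114 genes had both mutants on the same side of both controls, as had 46.2% of all genes tested, where chance gives 33.3%.

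**Figure D3:**
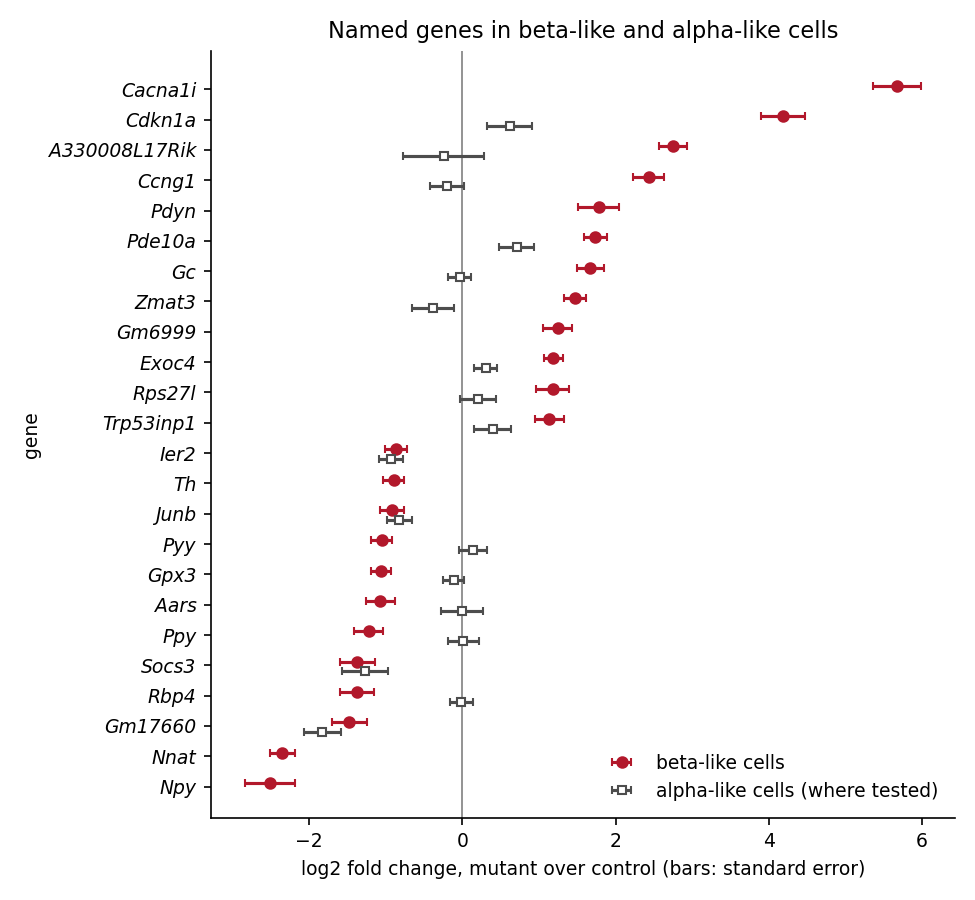
Log2 change, mutant over control, of the 24 genes of the fixed rule in beta-like cells and, where the gene was tested, in alpha-like cells; points are fitted values and bars 1 SE. Cacna1i had the largest rise (5.67) and Npy the largest fall (−2.51) among them in beta-like cells. Ppy and Pyy changed sign in settings with another treatment of doublets, which also redrew the classes.

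Of 28 gene lists fixed before the data were examined, 12 passed camera at its preset correlation, 2 upwards and 10 downwards. None of the 28 passed with an estimated correlation (lowest adjusted p = 0.492, 2 lists at an unadjusted p under 0.05) or by fry (lowest adjusted p = 0.111, 8 lists at an unadjusted p under 0.05). Known targets of Atf4, which serve amino acid synthesis, one-carbon metabolism and amino acid uptake, stood lower as a group. Of 40 members 33 had a negative log2 change, the median was −0.43, and camera gave an adjusted p of 1.00e-11 (adjusted p = 0.492 with an estimated correlation). Over all genes 0 of the 40 passed with edgeR (1 higher and 21 lower at an unadjusted p under 0.05; DESeq2 and limma-voom each called 2 lower). In the list alone, after adjustment, 1 rose and 19 fell. Asparagine synthetase, Asns, had 32.8 and 58.4 CPM in mutants 1 and 2 against 97.1 and 103 CPM in controls 1 and 2 (log2 change −1.13), and the amino acid transporter Slc7a5 16.6 and 33.2 against 57.5 and 61.5 CPM (−1.26). The serine synthesis enzyme Psph (−1.08) and the translation repressor Eif4ebp1 (−1.63) also fell when adjusted over the list alone (edgeR adjusted p = 0.00766 for each of these 4).

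The machinery of translation moved in part with them. Of 20 cytosolic tRNA synthetases, Aars fell over all genes and 7 fell adjusted over the list alone, among them Sars (−0.92), Yars (−0.82) and Gars (−0.74). The median was −0.25 (camera adjusted p = 5.37e-05; adjusted p = 0.538 with an estimated correlation). Of 83 ribosomal protein genes, Rpl3 (−0.83) fell and Rps27l rose over all genes, while 1 rose and 53 fell adjusted over the list alone, such as Rpl10a (−0.61) and Rpl10 (−0.53). Their median was −0.35, and it was −0.25 with library totals as the only scaling (camera adjusted p = 1.28e-27; adjusted p = 0.492 with an estimated correlation). Of 56 translation factors 0 passed over all genes with edgeR (5 higher and 11 lower at an unadjusted p under 0.05; DESeq2 1 and 5, limma-voom 0). With adjustment over the list alone 2 rose and 6 fell, including Eif3a (0.56), Eif3f (−0.62), Eef2 (−0.59) and Eef1a1 (−0.47). Camera gave that list an adjusted p of 0.246 (0.773 with an estimated correlation) with a median of 0.01 against a mean of −0.03, and 0.00962, downwards, without mutant 1.

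Beta cell identity genes, a question of the series, stood slightly lower. Of 35 members, Nnat fell over all genes. Adjusted over the list alone 1 rose, the prohormone convertase Pcsk1 (0.58), and 4 fell, Nnat, the channel Trpm5 (−0.67), Ins1 (−0.42) and Myt1 (−0.42). The fall of Ins1 cannot be told from an effect of the driver allele named at that locus, which the mutants alone carried. The median was −0.17 (camera adjusted p = 0.00413; adjusted p = 0.594 with an estimated correlation), and without mutant 1 the camera adjusted p was 0.0890. Of 30 genes of secretory granules and exocytosis 0 passed over all genes with edgeR (7 higher and 3 lower at an unadjusted p under 0.05; DESeq2 2 and 2, limma-voom 0). Within the list alone 3 rose and 2 fell after adjustment, including the calcium channel Cacna1c (0.61), Scg2 (0.46), Scg5 (−0.58) and Pcsk1n (−0.49). Camera gave an adjusted p of 0.132 (0.594 with an estimated correlation; 0.0291, upwards, without mutant 1) at a median of 0.10. Among 12 genes normally low in mature beta cells, the retinaldehyde dehydrogenase Aldh1a3 rose from 0.186 and 0.435 CPM in controls 1 and 2 to 5.38 and 4.38 CPM in mutants 1 and 2 (log2 change 3.91, edgeR adjusted p = 0.00565). In all 3 rose when adjusted over the list alone, with Cd81 (0.77) and Serpina7 (1.77). The list's median was −0.05, or 0.06 with library totals as the only scaling, and its mean 0.47 (camera adjusted p = 0.172, upwards; 0.565 with an estimated correlation).

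Hormones of the other islet cells fell in part. Of 6 genes, Ppy and Pyy fell over all genes, and adjusted over the list alone Sst (−0.73) fell as well and transthyretin, Ttr (0.42), rose, with a median of −0.44 (camera adjusted p = 0.0267; adjusted p = 0.492 with an estimated correlation). Sst was 0.08 with the looser cell filter and 0.01 with the stricter one. Ppy and Pyy also turned sign in the settings with other treatments of doublets given above. Of 12 alpha cell genes Gc rose over all genes and in the list alone, and the list had a median of −0.33 (camera adjusted p = 0.547; 0.773 with an estimated correlation).

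Among stress and growth control genes, 4 of 19 p53 targets and apoptosis regulators rose over all genes: Cdkn1a, Ccng1, Trp53inp1 and Bax, the pore-forming apoptosis protein (0.87, edgeR adjusted p = 0.0266). Adjusted over the list alone 5 rose, Mdm2 included (0.67), and Gadd45g (−0.69) fell. The median was 0.01, or −0.00 with totals that left out hormone and mitochondrial genes, and the mean 0.40. These values cover the 19 members, apoptosis regulators among them, and do not speak for p53 targets outside the list. Camera gave an adjusted p of 0.0386 (adjusted p = 0.492 with an estimated correlation), and of 0.0518 without mutant 2. Immediate early genes, which tissue dissociation induces, stood lower. They shared a list with heat shock genes, which did not all move with them: Dnajb1 stood at −0.34, Hspa1a at −0.15, Hspa1b at 0.12 and Hsph1 at 0.31, none past edgeR over all genes or the list alone. Of the 22 members Ier2, Socs3 and Junb fell over all genes. Adjusted over the list alone 1 rose and 8 fell, with Dusp1 at −0.61 and a median of −0.35 (camera adjusted p = 4.52e-06; adjusted p = 0.492 with an estimated correlation). Of 37 endoplasmic reticulum chaperone genes 0 passed with edgeR over all genes or the list alone (2 higher and 5 lower at an unadjusted p under 0.05; DESeq2 and limma-voom 0). Their median was −0.00, or 0.10 with library totals as the only scaling, and camera gave 0.547 (0.926 with an estimated correlation; 0.0270, downwards, without mutant 1). None of 13 cell cycle genes passed with edgeR over all genes or the list alone, had an unadjusted p under 0.05 or was called by DESeq2 or limma-voom. Their median was −0.04, or 0.07 with library totals, and their mean 0.06 (camera 0.886, upwards; 0.937 with an estimated correlation). Of 24 autophagy and lysosome genes 0 passed with edgeR over all genes or the list alone (1 lower at an unadjusted p under 0.05; DESeq2 and limma-voom 0). Their median was −0.08, or 0.03 with library totals (camera 0.101; 0.564 with an estimated correlation; 0.0311, downwards, without mutant 2). Of 19 interferon and antigen presentation genes 0 passed in the same 2 ways (2 lower at an unadjusted p under 0.05; DESeq2 and limma-voom 0). Their median was −0.04, or 0.06 with library totals (camera 0.101; 0.594 with an estimated correlation; 0.0125, downwards, without mutant 1).

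Metabolic lists held single genes that changed. Of 24 antioxidant genes Gpx3, Mt2 (−0.83, edgeR adjusted p = 0.0280) and Mt1 (−0.63, 0.0398) fell over all genes. Adjusted over the list alone 2 rose, with the regulator Nfe2l2 at 0.66, and 4 fell (median −0.12; camera adjusted p = 0.0267; adjusted p = 0.492 with an estimated correlation; camera 0.0831 without mutant 2). Ppargc1a, a coactivator of mitochondrial genes, rose from 8.73 and 3.48 CPM in controls 1 and 2 to 21.5 and 20.5 CPM in mutants 1 and 2 (1.79, edgeR adjusted p = 0.0417), alone among 24 fatty acid oxidation genes. That list's median was 0.01, or −0.00 with totals that left out hormone and mitochondrial genes, and its mean 0.06 (camera 0.878, downwards; 0.926 with an estimated correlation). Of 35 genes of fatty acid synthesis and storage 0 passed over all genes with edgeR (0 higher and 2 lower at an unadjusted p under 0.05; DESeq2 1 lower, limma-voom 0). The lipid receptor Ffar4 (−1.55) and lipoprotein lipase, Lpl (−0.83), fell adjusted over the list alone. The median was −0.05, or 0.05 with library totals (camera 0.172; 0.564 with an estimated correlation). None of 24 cholesterol synthesis genes passed with edgeR over all genes or the list alone (1 higher and 2 lower at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). Their median was −0.12 (camera 0.171; 0.663 with an estimated correlation; 0.0206, downwards, without mutant 1). Nuclear genes of the respiratory chain had 0 of 76 past edgeR over all genes or the list alone (2 higher and 4 lower at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). Their median was −0.06, or 0.05 with library totals as the only scaling (camera adjusted p = 0.0432; adjusted p = 0.773 with an estimated correlation). Camera gave 0.657 without mutant 2, 0.0509 without control 1 and 0.675 without control 2. The 12 genes of the mitochondrial genome had 0 past edgeR over all genes or the list alone (0 at an unadjusted p under 0.05, by DESeq2 and by limma-voom). Their median was −0.11, or 0.03 with library totals, and their mean 0.02 (camera 0.848, downwards; 0.937 with an estimated correlation). That list moved with the controls. Camera gave 2.89e-07, upwards, without control 1 and 2.13e-07, downwards, without control 2.

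**Figure D4:**
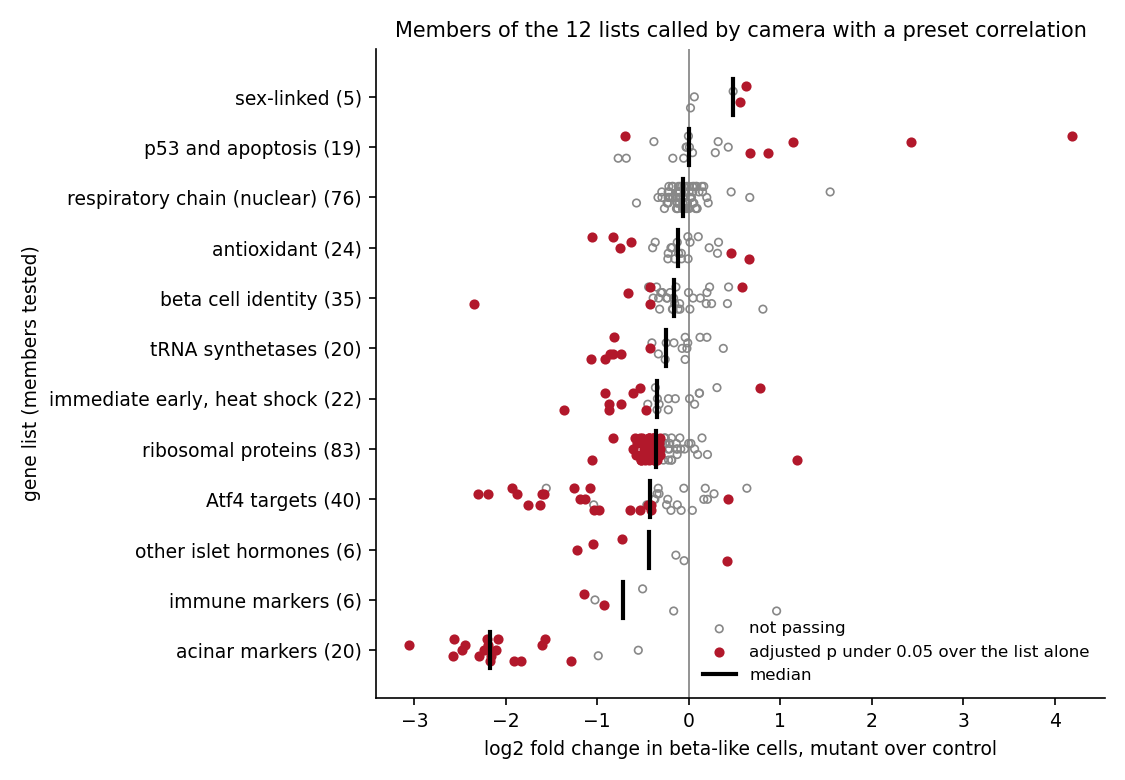
Log2 change, mutant over control, of every tested member of the 12 gene lists that passed camera at its preset correlation in beta-like cells; filled points passed adjusted over the list alone and black bars are medians. Medians ran from −2.17 for acinar markers to 0.49 for sex-linked genes, and 0 of the 12 lists passed with an estimated correlation.

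Markers of other cell types moved with the groups as well. Of 20 acinar genes, which encode digestive enzymes, 12 fell over all genes and 18 adjusted over the list alone (median −2.17; camera adjusted p = 6.63e-24; adjusted p = 0.492 with an estimated correlation), led by Ctrb1 (−2.21), Prss2 (−2.23), Cela1 (−2.11) and Amy2a5 (−1.91). Acinar genes took 30.8 and 29.2 CPM of the beta-like counts of mutants 1 and 2 and 99.9 and 166 CPM of those of controls 1 and 2. Of the 114 changed genes 102 lay outside that list. The count is 101 when 2210010C04Rik, a leading gene of the unnamed cluster 10 that the list left out, is set with it. Of 6 immune genes 0 passed over all genes with edgeR (3 lower at an unadjusted p under 0.05; DESeq2 1, limma-voom 0). Cd79a (−1.14) and C1qa (−0.92) fell adjusted over the list alone, and the median was −0.71 (camera 0.0259; adjusted p = 0.492 with an estimated correlation). The osteopontin gene Spp1 (2.81) alone rose among 6 duct genes adjusted over the list alone, with 0 past edgeR over all genes (1 higher at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). Their median was 0.17 (camera 0.171, upwards; 0.584 with an estimated correlation; 0.0101 without mutant 2 and 0.00914 without control 2). None of 7 endothelial, 4 mesenchymal and 3 erythroid genes passed with edgeR, over all genes or the list alone, or had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their medians were −0.12, −0.24 and 0.69 (camera 0.615, 0.547 and 0.0650; 0.773, 0.854 and 0.594 with an estimated correlation; 0.000430, upwards, for the erythroid genes without control 2). Of 5 sex-linked genes 0 passed over all genes with edgeR (3 higher at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). Eif2s3y (0.56), which is Y-linked, and Xist (0.63), which marks female cells, rose adjusted over the list alone (camera 0.0448; adjusted p = 0.570 with an estimated correlation; camera 0.320 without mutant 2 and 0.239 without control 2).

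In alpha-like cells, a type that does not normally express Ins1, the chaperone Hsp90aa1 rose from 464 and 380 CPM in controls 1 and 2 to 812 and 726 CPM in mutants 1 and 2 (log2 change 0.86 ± 0.151 SE, edgeR adjusted p = 0.0146), and the heat shock gene Hspa1b rose as well (0.78 ± 0.146, 0.0253). Zc3h12b (1.96 ± 0.333, 0.0116) and Klhl29 (1.48 ± 0.266, 0.0171) also rose. The acinar genes Amy2a5 (−1.98, edgeR adjusted p = 0.00281) and Ctrb1 (−1.93, 0.00987) and the predicted gene Gm17660 (−1.83, 0.00281) fell, as did the immediate early genes Ier2 (−0.92, 0.0116) and Fosb (−0.85, 0.0230) and the uroplakin Upk3a (−1.10, 0.0499). In all, 4 genes rose and 11 fell of 8837 tested. Atf4 stood at 243, 274, 427 and 321 CPM in mutant 1, mutant 2, control 1 and control 2 (−0.53 ± 0.165, edgeR adjusted p = 0.305). Acinar genes took 47.1 and 52.7 CPM of alpha-like counts in mutants 1 and 2 and 166 and 263 CPM in controls 1 and 2.

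Of 24 lists tested in alpha-like cells, 4 passed camera at its preset correlation, all downwards. They were ribosomal proteins (median −0.17, camera adjusted p = 5.33e-11; adjusted p = 0.697 with an estimated correlation) and mitochondrially encoded genes (−0.37, 0.000337; 0.776 with an estimated correlation). Immediate early and heat shock genes (−0.52, 3.86e-06; 0.707 with an estimated correlation) and acinar markers (−1.97, 1.33e-17; 0.277 with an estimated correlation) were the others. Of the 21 immediate early and heat shock genes Hspa1b rose and 3 fell over all genes, and of 8 acinar genes 5 fell. Targets of Atf4 had a median of −0.09, with 0 of 25 past edgeR over all genes or the list alone (camera 0.320; 0.776 with an estimated correlation). The count of 15 genes rose whichever pool was left out, in fits where edgeR used the common spread for every gene. Those fits do not show the weight of any pool. Calls ended for Upk3a without mutant 1 (edgeR adjusted p = 0.0843), for Klhl29 without mutant 2 (0.0997), and for Hsp90aa1, Fosb and Hspa1b without control 2 (0.0648, 0.0911 and 0.121).

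Some effects differed between beta-like and alpha-like cells when the difference itself was tested. Cdkn1a rose by 3.55 ± 0.324 (SE, edgeR adjusted p = 4.24e-06) more on the log2 scale in beta-like than in alpha-like cells, and Ccng1 by 2.57 ± 0.237 (4.24e-06). It was 2.97 ± 0.492 for A330008L17Rik (edgeR adjusted p = 0.00839), 1.81 ± 0.282 for Zmat3 (0.00425), 1.68 ± 0.185 for Gc (5.94e-05) and 1.39 ± 0.261 for the G protein regulator Rgs4 (0.0228). In the other direction the differences were −1.41 for Rbp4, −1.23 for Ppy and −1.20 for Pyy. Under other treatments of doublets the differences of Ppy and Pyy did not hold: with called doublets kept they were −0.10 and −0.17 (edgeR adjusted p = 0.907 and 0.740), and with the highest doublet scores removed 0.19 and 0.25 (0.932 and 0.907). These settings also redrew the clusters and classes. With called doublets kept, alpha-like cells went from 108, 202, 135 and 118 in mutant 1, mutant 2, control 1 and control 2 to 194, 346, 240 and 218. The cause was not tested. With the highest scores removed, calls also ended for A330008L17Rik (edgeR adjusted p = 0.0721), Gpx3 (0.0747) and Rpl22l1 (0.0599). The differences were −1.06 for the transcriptional coregulator Cited2, −0.97 for Gpx3 and −0.93 for the ribosomal protein paralogue Rpl22l1 (edgeR adjusted p 0.000341 to 0.0472 for these 6 genes). In all, 15 genes had the higher and 9 the lower effect in beta-like cells, of 13346 tested. The count of 24 became 94 without mutant 2 and 60 without control 2, both with the common spread for every gene. Calls ended for Cited2 and Rpl22l1 without mutant 1 (edgeR adjusted p 0.142 and 0.260), for Zmat3, Cited2 and Rpl22l1 without control 1 (0.0654, 0.237 and 0.0606) and for A330008L17Rik without control 2 (0.154). Of 27 lists, 9 passed camera at its preset correlation in this test and 0 with an estimated one. Lower effects in beta-like cells were found for Atf4 targets (median −0.30, camera adjusted p = 9.03e-06; 0.590 with an estimated correlation), tRNA synthetases (−0.29, 0.00239; 0.418 with an estimated correlation) and ribosomal proteins (−0.20, 5.23e-27; 0.354 with an estimated correlation). The same held for other islet hormones (−0.07, camera adjusted p = 0.0112; 0.418 with an estimated correlation), respiratory chain genes (−0.12, 0.00131; 0.726 with an estimated correlation) and immune genes (−1.30, 0.00550; 0.418 with an estimated correlation). Higher effects were found for mitochondrially encoded genes (0.27, camera adjusted p = 9.57e-10), p53 targets (0.14, 0.00870) and duct genes (0.46, 0.00226), each at 0.418 with an estimated correlation.

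Delta-like and PP-like cells held some of the beta-like changes, as did endothelial-like and macrophage-like cells for Cdkn1a. In delta-like cells Cdkn1a rose from 9.94 and 32.5 CPM in controls 1 and 2 to 209 and 107 CPM in mutants 1 and 2 (log2 change 2.88, edgeR adjusted p = 0.000593). Cacna1i stood at 2.99, A330008L17Rik at 1.79, Ccng1 at 1.49, Pde10a at 1.35 and Pdyn at 1.08 among the 10 genes that rose. Npy (−2.79), Nnat (−1.13), Atf5 (−1.43) and Atf4 (from 297 and 280 to 128 and 160 CPM, edgeR adjusted p = 0.00419) were among the 9 that fell. In PP-like cells 6 rose and 5 fell, Cdkn1a from 34.9 and 45.6 to 228 and 193 CPM (2.40, edgeR adjusted p = 4.82e-05) and Atf4 from 369 and 379 to 142.5 and 192 CPM (−1.15, adjusted p = 0.0123). These genes were chosen after their values were seen. Delta-like cells shared 8 of 10 rises and 7 of 9 falls with beta-like cells, where independent sets would share 0.0598 and 0.0274. PP-like cells shared 4 of 6 and 2 of 5 (0.0377 and 0.0148). Alpha-like cells shared 1 of 4 rises and 8 of 11 falls with beta-like cells (0.0214 and 0.0338), the acinar genes Amy2a5, Cela1, Ctrb1, Prss2 and Try5 among the falls, so shared falls were not particular to the other 2 classes. The sums came from the same 4 pools, which adds to such overlaps. Ins2 in delta-like cells reached 43.2 to 46.8% of its beta-like level and in PP-like cells 45.3 to 63.1%. In alpha-like cells it reached 2.44 to 6.04%. It reached 66.9 to 92.7% in endothelial-like and 50.8 to 86.9% in macrophage-like cells, whose genes were not tested. There too Cdkn1a was higher in mutants 1 and 2 than in controls 1 and 2, before TMM scaling. It had 467 and 190 against 67.7 and 69.8 CPM in endothelial-like cells. In macrophage-like cells it had 397 and 279 against 34.6 and 58.8 CPM. The PP-like class was a changing mix, since glucagon RNA, Gcg, at 84478 to 111804 CPM, stood above Ppy in every sample (43684 and 14122 CPM in mutants 1 and 2, 48244 and 19722 CPM in controls 1 and 2), which bears on its 11 genes. Acinar genes were higher in both controls than in both mutants in delta-like cells (123 and 166 against 39.2 and 40.9 CPM) and in PP-like cells (120.0 and 213 against 26.1 and 40.5 CPM). The 19 delta-like genes became 52, 101, 119 and 96 without mutant 1, mutant 2, control 1 and control 2, all with the common spread for every gene. Their calls ended for Kcnip1 and 9030617O03Rik without mutant 1 (0.0793 and 0.136) and for Npy without control 1 (edgeR adjusted p = 0.153). The 11 PP-like genes became 6, 12, 30 and 54, the last with the common spread. Calls ended for 8 of them without mutant 1, Atf4 (0.174), Ccng1 (0.111) and Pde10a (0.0706) included, for 6 without mutant 2, for 2 without control 1 and for 1 without control 2 (edgeR adjusted p 0.0510 to 0.594).

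Cell type shares were compared with an exact permutation test, whose smallest p for 2 against 2 samples is 0.333, so no difference could reach 0.05. Beta-like cells made up 54.6 ± 4.11% of mutant cells and 58.0 ± 6.08% of control cells (mean ± SD, n = 2 per group; exact permutation p = 0.667 on both sides). Alpha-like cells made up 9.78 ± 2.87% against 6.54 ± 0.321%, delta-like cells 11.3 ± 1.10% against 7.88 ± 0.772%, PP-like cells 9.27 ± 0.939% against 6.69 ± 1.67% and macrophage-like cells 4.70 ± 3.09% against 1.77 ± 0.448%, each higher in both mutants than in both controls (exact permutation p = 0.333 for each). Endothelial-like cells made up 4.87 ± 1.71% against 4.44 ± 2.95% (exact permutation p = 1). Stellate-like cells were 16 of 1394 and 6 of 1711 cells in the mutants and 0 of 1994 and 0 of 1868 in the controls, whose upper 95% Clopper-Pearson limits were 0.185% and 0.197%. The absence depended on the setting: the controls had 4 and 6 such cells at the finer clustering (0.201% and 0.321%) and 9 and 9 with the looser filter (0.349% and 0.384%), and with the stricter filter no sample had any. Clusters left without a name were 9 and 10, with acinar genes leading cluster 10. They made up 3.87% and 5.49% of cells in mutants 1 and 2 and 10.8% and 18.5% in controls 1 and 2. They take from the shares of all other classes. Their Ins2 levels, 294073 and 265021 CPM, lay within the 160354 to 327689 CPM of the beta-like clusters. Acinar markers made up only 0.161% of the counts of cluster 10, so it was not taken for acinar cells. Both clusters may hold beta cells, which bears on the beta-like shares. In the mutants cluster 9 was the larger (43 and 57 cells against 11 and 37), and in the controls cluster 10 (179 and 305 cells against 37 and 41). The beta-like difference of −3.36 percentage points was 0.934 without control 1, 1.48 with called doublets kept and 2.14 with the looser cell filter. The endothelial-like one of 0.424 was −0.786 without mutant 2, −1.66 without control 1 and −0.637 with the looser filter. The PP-like one of 2.58 was −0.474 at the finer clustering and −1.35 with called doublets kept. Leaving out 1 sample moved the alpha-like difference of 3.23 to 1.20 without mutant 2 and 5.26 without mutant 1, the PP-like one to 1.40 without control 2, and the macrophage-like one of 2.93 to 0.742 without mutant 1 and 5.12 without mutant 2. The macrophage-like difference was 0.875 at the finer clustering, where that class held 31 cells of mutant 1 in place of 96. The leading genes of the macrophage-like cluster included the immunoglobulin gene Igkc, so the class may not be macrophages alone. Under the other settings of clustering, doublets and filters, alpha-like cells made up 14.2 to 17.0% of mutant and 10.2 to 11.8% of control cells as group means. With the stricter filter delta-like cells were no longer higher in both mutants (13.6% and 17.2% against 14.5% and 12.5%, exact permutation p = 0.667).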

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

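Chosen only after the result was seen were the tests of the Ins1 share in mutant 2, of free RNA, of a library difference within mutant 2 and of beta cell RNA in other barcodes. The effect of the mutation differed between beta-like and alpha-like cells, as a log2 difference tested with edgeR, by 3.55 for Cdkn1a, 2.97 for A330008L17Rik, 2.57 for Ccng1, 1.81 for Zmat3, 1.675 for Gc and 1.39 for Rgs4. It differed by −1.41 for Rbp4, −1.23 for Ppy, −1.20 for Pyy, −1.06 for Cited2, −0.967 for Gpx3 and −0.926 for Rpl22l1. With called doublets kept the differences of Ppy and Pyy were −0.0976 and −0.170, and with the highest doublet scores removed 0.185 and 0.246, none of which passed edgeR after adjustment.

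Beta-like cells of mutant 2 held 2 kinds of cell, 51.0% of deep cells with no Atf4 count and 29.3% with at least 3. Mice without Ins1Cre in the pool may explain this: cells with at least 3 Atf4 counts had gone 100.34% of the way from the Ins1 share of mutant 1 to that of the controls (93.0 to 108%), which assumes that loss of Atf4 does not itself lower Ins1. The share was corrected for UMI collisions, but these cells were deeper than those with no Atf4 count (median 18129.5 against 15159 UMIs). The highest values are also near saturation. In the cells with at least 3 Atf4 counts Cdkn1a stood at 88.1, Cacna1i at 16.9 and Nnat at 51.6 CPM before TMM scaling. All beta-like cells of controls 1 and 2 had 15.5 and 26.0, 1.21 and 1.47, and 140 and 140 CPM. These genes, chosen with their values known, did not reach the control levels, so the Ins1 share alone does not settle this. Cdkn1a and Cacna1i do not settle it either, as other barcodes of mutant 2 also held their RNA. They had 190 and 28.2 CPM in endothelial-like, 279 and 42.9 in macrophage-like and 189 and 37.8 in PP-like cells. In delta-like cells they had 106 and 26.6 CPM, but in alpha-like cells only 43.7 and 1.62 CPM. Carried RNA would not by itself account for the low Nnat. Deletion at an equal rate in all mice of the pool was set aside, because cells with and without Atf4 counts differed in sex (Fisher's exact p = 6.16e-27), which leaves open incomplete deletion in the male mice alone. Free RNA carrying Atf4 into all beta-like cells was set aside as well, since Atf4 was 18.6 times as high in cells with Y-linked counts as in cells with Xist (12.1 to 30.2).

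Genes changed in beta-like cells did not come only from a difference shared by all cells of a library, which would leave those cells alike. Differences between mice of a pool are not covered, since cells with and without Atf4 counts may come from different mice, also among males. Within mutant 2, cells with no Atf4 count differed from cells with at least 3 in the direction of the main comparison. The median log2 difference was 0.512 over the called genes (95% interval of a bootstrap over genes 0.249 to 0.757) and 0.0116 over genes not called. Such an interval holds no spread between mice. In cells with Y-linked counts alone, so of 1 sex, the median was 0.594 (0.339 to 0.761). Whether a library difference made the larger part could not be told, as the median within mutant 2 was 37.4% of that between the groups (18.2 to 55.3%). It was 40.7% for the rises, 25.4% for the falls and 54.1% for the falls outside the acinar genes. The change between groups was a fitted value of genes chosen for passing. Within mutant 2 it was a ratio of summed counts with 1 count added, so the percentage does not measure the part of a library difference. The Ins1Cre allele rather than the loss of Atf4 could not be tested, because 0 deep cells of mutant 1 had at least 3 Atf4 counts, the cells with the allele and with Atf4 that such a test needs.

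Genes changed in delta-like and PP-like cells may in part be beta cell RNA in those barcodes. With acinar genes left out, the observed differences were a median of 1.17 times those that beta cell RNA would carry over 15 of 19 delta-like genes (0.708 to 19.8 times) and 1.39 times over 9 of 11 PP-like genes. Between 0.5 and 1.5 times lay 10 of the 15 and 6 of the 9. Above lay Cldn11 (19.8), Stk32a (3.92), Gm17660 (2.81), Kcnip1 (2.58) and Pde10a (2.56) in delta-like cells and Fosb (6.89), Dnajc1 (2.78) and Cldn6 (−32.9 CPM against −0.0320 carried) in PP-like cells, as did the acinar genes (2.28 to 3.40). Whether these genes also changed in delta-like and PP-like cells themselves was left open.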

How the results depend on the processing

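Settings added only after results were seen were the correction for UMI collisions, removal of the highest doublet scores, removal of the beta-like cluster of fewest genes, cells split by Xist and Y-linked counts, equal weight per cell, cells matched for depth, and both treatments of doublets for the difference between beta-like and alpha-like cells. The cause of each change was not tested. In cells with Y-linked counts, though, Atf4 stood at 188 CPM in mutant 2 against 2.96 CPM in mutant 1, so the mutants were unlike in that setting. The 114 genes changed in beta-like cells became 238 with DESeq2, 226 with library totals only (184 up, 42 down), 43 with no low-count filter, 67 with the stricter cell filter and 74 without the beta-like cluster of fewest genes. They became 182 in cells with Xist, 16 in cells with Y-linked counts, 177 with equal weight per cell, 304 with a replicate block, 383 with a library prefix block, and 78 to 503 without 1 sample. The 15 of alpha-like cells became 4 with DESeq2, 86 with no low-count filter, 81 with the prefix block and 52 to 63 without 1 sample. The 19 of delta-like cells became 8 with DESeq2, 100 with no low-count filter and 52 to 119 without 1 sample, and the 11 of PP-like cells 4, 67 and 6 to 54. The 24 that differed between beta-like and alpha-like cells became 12 with DESeq2, 73 with no low-count filter, 60 with doublets kept and 28 to 94 without 1 sample, and with the highest doublet scores removed the difference turned to 0.185 for Ppy and 0.246 for Pyy. The 12 gene lists became 0 with camera at an estimated correlation, 0 with fry and 10 to 16 without 1 sample, and respiratory chain genes lost their call with the replicate block (camera adjusted p = 0.101). The targeted gene Atf4 was −6.41 in cells with Xist, −3.96 with the replicate block, where it passed (edgeR adjusted p = 0.00918), and −7.68 to −1.67 without 1 sample. Ins1 was −0.438 with the prefix block, where it passed (edgeR adjusted p = 0.0119), and −0.668 to −0.235 without 1 sample. The labels do not say what the replicate number or the prefix marks, and each block left 1 residual degree of freedom. Deviations of mutant 1 correlated at −0.0560 with control 1 (same number) and at 0.0560 with control 2 (same prefix). Neither block was therefore shown to pair the samples, and calls made with them do not offset the main fit. Ins2 turned to 0.0125 with library totals and 0.0329 with equal weight per cell, and ranged from −0.211 to 0.00386 without 1 sample. Ppy turned to 0.00856 with doublets kept and 0.119 with the highest doublet scores removed, Pyy to 0.281 with the latter, Scg5 to 0.0488 in cells with Xist, and Sst to 0.0791 with the looser and 0.00940 with the stricter cell filter. Mitochondrially encoded genes turned upwards without control 1 (camera adjusted p = 2.89e-07; 2.13e-07 to 0.225 without 1 sample). The share of beta-like cells turned to 1.48 with doublets kept and 2.14 with the looser cell filter (−7.66 to 0.934 without 1 sample), PP-like to −0.474 at resolution 2 and −1.35 with doublets kept (1.40 to 3.76), and endothelial-like to −0.637 with the looser filter (−1.66 to 2.51, and −0.786 without mutant 2). Shares of alpha-like (1.20 to 5.26 without 1 sample), delta-like (2.67 to 4.22) and macrophage-like cells (0.742 to 5.12) kept the sign of their mean difference, but not its size. Alpha-like became 5.203 with doublets kept and 5.00 with the looser filter, macrophage-like 0.875 at resolution 2 and 1.89 with doublets kept. Delta-like became 2.17 with the looser and 1.92 with the stricter filter, where control 1 (14.5%) stood above mutant 1 (13.6%), and PP-like 0.183 with the latter. No PP-like class formed at resolution 0.5, with the highest doublet scores removed or with the looser filter.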

Other observations

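The genes and cells described here, and the test of neighbouring genes, were chosen only after the result was seen. Lowly expressed genes were among those raised in mutant beta-like cells, and the 5 given here were chosen with their values known. Phlda3, an inhibitor of Akt signalling, stood at 39.6 and 30.7 CPM in mutants 1 and 2 and at 1.30 and 1.48 CPM in controls 1 and 2 (log2 change 4.65 ± 0.228 SE, edgeR adjusted p = 6.27e-05). The death receptor Eda2r stood at 8.32 and 5.53 against 0.743 and 0.348 CPM (edgeR adjusted p = 0.00565), the exonuclease Aen at 16.1 and 9.29 against 2.51 and 3.48 CPM (0.0228) and the DNA polymerase Polk at 28.4 and 22.8 against 14.0 and 9.92 CPM (0.0421). The Ddit4-like gene Ddit4l stood at 17.0 and 8.77 against 0.836 and 0.609 CPM (edgeR adjusted p = 0.00305).

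Within mutant 2, cells with no Atf4 count and cells with at least 3 could be set side by side in the same pool. Cdkn1a stood at 516 CPM in the former (95% Poisson interval 494 to 539) and at 88.1 CPM in the latter (77.1 to 100.3). Ccng1 stood at 351 and 94.3, Cacna1i at 92.4 and 16.9, Phlda3 at 49.7 and 10.4, Zmat3 at 114 and 46.2, and Bax at 123 and 59.6 CPM. Rbp4 stood at 23.6 and 56.6 CPM, Nnat at 19.8 and 51.6, Aars at 41.9 and 85.0 and Rpl3 at 149 and 251 CPM. The hormones Ppy, at 69.5 and 236 CPM, and Pyy, at 124 and 299 CPM, were also higher in cells with at least 3 Atf4 counts. RNA of other islet cells may thus differ between these cells, which bears on the delta marker Rbp4. Of the 114 genes called in the main comparison 77 (67.5%) moved in its direction here. Some did not follow the Atf4 counts: Pde10a stood at 198 and 241 CPM, Junb at 144 and 119, Th at 40.4 and 36.2, and Ier2 at 77.4 and 43.1 CPM. These are values of 1 pool, so the intervals hold counting error alone.

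Cacna1i lies 29.7 kb downstream of Atf4, and its rise could be an effect of the deleted allele on its chromosomal neighbours rather than of the lost protein. The data could not tell. Of other genes within 100 kb of Atf4, 1 of 4 had an unadjusted edgeR p under 0.05 (Fisher's exact p = 0.468), against 14.6% of genes elsewhere. The share was 3 of 6 within 200 kb (Fisher's exact p = 0.0440), 6 of 12 within 500 kb (0.00402) and 10 of 29 within 1000 kb (0.00605). Of those 10 genes 9 were lower in the mutants and 1 was higher, so they moved against Cacna1i. A mutant that lacks the Atf4 protein with the locus intact would separate these explanations.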
